A study of Mus musculus with 9 samples.

How the data were processed

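RNA was measured by sequencing in cultured mandibular periosteal progenitor cells of the mouse, in 9 libraries that the labels place in 3 groups of 3. The groups were Plagl1 fl/fl control cells without induction (day 0), the same genotype after 3 days in osteogenic medium, and CTSK-iCre;Plagl1 fl/fl mutant cells after the same 3 days. The medium held 5 mM b-glycerophosphate, 50 ug/ml ascorbic acid and 100 nM dexamethasone. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with an NEBNext Ultra II RNA kit. Nothing in the labels says that the 3 libraries of a group came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical.

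Per the submitters' processing notes, the authors used cutadapt, HISAT2 and HTSeq with genome build GRCm39; versions, the annotation release and the strand setting of the counting are not given in the sources used here. The deposited table holds whole read counts per gene and library, not normalized, and beside them FPKM values. The deposited FPKM value was checked for 11879 to 12199 genes per library, those with more reads. It equalled the count divided by the gene's length and by 1 total per library. That total was close to the library's summed count, such as 18851020 against 18850989 in control day 3 replicate 1. FPKM thus carried no further normalization there and was used only for this check. The table paired gene identifiers with symbols for 21958 genes, and 1 further line, empty in the copy used here, was left out. Xist, H19 and Meg3, among others, were not analysed here. No column of per-sample values was left unused. Where several identifiers shared a symbol, the symbol went to the identifier with most reads, and the other 23 carried their identifier as well. Reads from members of close gene families, such as Serpina3, Saa and Ly6, and from genes that overlap on opposite strands may be shared or split by the counting, so their single values are uncertain.

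The total count per library ran from 16204327 to 19859744. A floor of 3 counts corresponded to 0.146 to 0.186 CPM (counts scaled to library size), and intervals and floors cover counting error only. The 13013 genes passing edgeR's filterByExpr (minimum count 10, by group) held at least 99.96% of the reads of each library. Counts were scaled by TMM factors (0.960 to 1.07) and fitted in edgeR 4.0.16 (R 4.3.3) with a quasi-likelihood model holding 1 mean per group over all 9 libraries. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called. The contrasts were control day 3 against control day 0, mutant day 3 against control day 3, and mutant day 3 against control day 0. Log2 fold changes are given with their standard errors, taken as the fold change over the root of the F statistic, and CPM values as mean ± SD over 3 libraries. Where a group held 0 reads, the fold is a lower bound against 3 counts over the group. Where it held 1 to 3 reads, the ratio has a 95% exact binomial counting interval.

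Fixed before the data were examined were the design, the alternatives, the rule for named genes and 29 gene lists. The rule names Plagl1 first, then for each of the first 2 contrasts the 10 genes with the largest log2 fold change in each direction. These needed an adjusted p below 0.05, a mean of at least 5 CPM, group values that do not overlap and a symbol that is not a predicted name. It also names up to 4 members of each list with the smallest p, or the 2 most abundant members for lists of other cell types. Some genes that the rule names are not reported here. Of the genes called in both contrasts it names the 5 with the smallest larger p that moved in opposite directions and the 5 that moved the same way. The lists covered osteoblast differentiation, periosteal progenitors, collagen matrix, chondrocytes, adipocytes, glucocorticoid response, cell cycle, an imprinted gene network, BMP and TGF-beta, Wnt, hedgehog and Notch, IGF, interferon response, inflammation, glycolysis, oxidative phosphorylation, the secretory endoplasmic reticulum, mandibular patterning, Hox genes, osteoclasts, macrophages, endothelium, skeletal muscle, smooth muscle and pericytes, epithelium, Schwann cells, erythroid cells, mitochondrial transcripts and immediate early genes. Of their 473 distinct genes 6 had no row, and 3 were matched through a synonym. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, inter-gene correlation 0.01), adjusted over lists, and again with an estimated correlation. Some lists share members. KEGG pathways were tested in the same way after the data were seen.

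The gene test was checked on simulated counts with planted changes, 49 or 50 genes at each fold. Far fewer genes changed there than were called in the data, so the shares below hold for that setting only. For control day 3 against day 0, over 12852 genes, 79.6% of 1.5-fold and 89.8% of 2-fold changes were called in the right direction, and 8.86% of the calls were false. For mutant against control at day 3, over 12866 genes, these values were 83.7%, 98.0% and 6.83%. At 1.2-fold, 22% were recovered in each. In separate simulations over 12870 and 12871 genes, camera called 0 of 20 random lists and called a planted list of genes raised 1.5-fold in each of the 2 contrasts. Counts there were drawn independently for each gene, so the check could not show false list calls that correlated genes would give. Every pair of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom of 2.69 to 11.3 over at least 12774 genes, so none is a repeated read-out of another library. This does not show separate cultures, since 2 libraries made from 1 RNA would also differ by more than sampling noise. All 9 were kept as the labels give them. Alternatives were other scalings and filters, DESeq2 1.42.0, limma-voom, only the 2 groups compared, a replicate block, a log2 change of at least 1, an estimated correlation and fry for the lists, and leaving out each library. The 2 alternatives planned for a table of normalized values only did not apply.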

Results

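The series measured gene expression in periosteal progenitor cells of the mouse mandible, the cells of the membrane that covers bone. It covered control cells before and after induction towards osteoblasts, and induced mutant cells in which Plagl1 was to be deleted. Plagl1 encodes a zinc-finger transcription factor and is an imprinted gene. The mutant carried a Cre recombinase under the Ctsk promoter, which is active in periosteal stem and progenitor cells and in osteoclasts, together with floxed Plagl1. There were 3 control libraries at day 0, 3 control libraries after 3 days in osteogenic medium and 3 mutant libraries after the same 3 days. Total counts were 16204327 to 19859744 per library, and between 14847 and 15123 genes had at least 1 read. Replicates lay close together, with a biological coefficient of variation of 0.0558 over the 3 groups. Estimated in each group alone it was 0.0494 in day 0 controls, 0.0425 in day 3 controls and 0.0715 in the mutant. The shared fit may thus understate the spread of the mutant libraries. On the first principal component of log2 CPM, which held 85.7% of the variance, the day 0 libraries lay apart from all day 3 libraries, and the second, with 5.54%, parted mutant from control at day 3.

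Plagl1 (ENSMUSG00000019817, chromosome 10, 12936248 to 13007438, plus strand, GRCm39) was read in all 9 libraries. In the control libraries at day 0 it had 35.5, 38.4 and 35.9 CPM, and at day 3 it had 43.9, 44.9 and 45.8 CPM. In the mutant libraries it had 26.3, 24.2 and 24.8 CPM. It was thus lower in all 3 mutant libraries than in any control library, at 0.559 times the control level of day 3 (log2 fold change −0.84 ± 0.07 SE, edgeR adjusted p = 7.6e-09). The counts cover the whole gene, and the position of the floxed part is not given in the sources used here, so the remaining counts cannot be split between transcripts that lack it and cells in which the gene is intact. Ctsk itself, whose promoter drives the Cre, was at 0.816 times the control level (−0.29, adjusted p = 0.001).

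**Figure D1:**
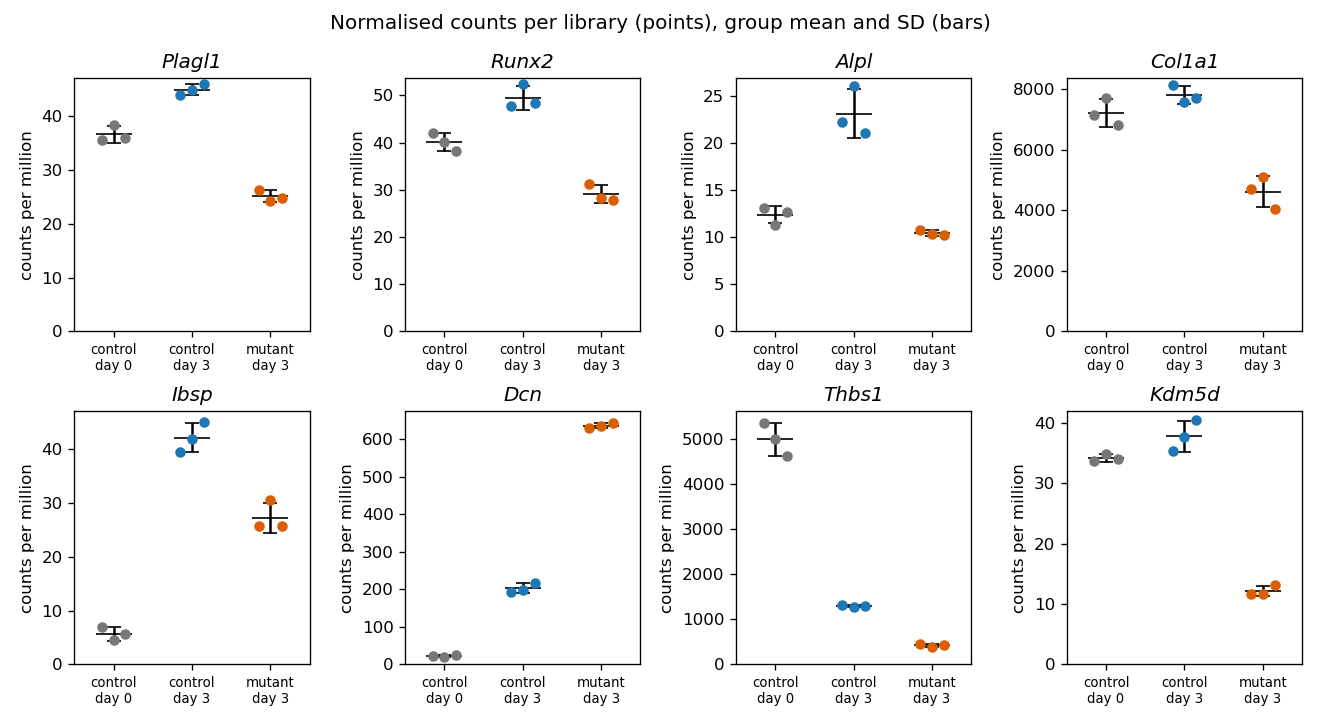
CPM (vertical axes, from 0) of 8 genes in each library of the 3 groups, with the group mean and SD as bars (n = 3). Plagl1, Runx2, Alpl, Col1a1 and Ibsp were lower in all 3 mutant libraries than in the day 3 controls, as was the Y-linked gene Kdm5d, while Dcn was higher in the mutant.

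The first comparison asked what 3 days of induction changed in control cells. The genes that rose most from day 0 included several that encode acute-phase or innate immune proteins. Serpina3m (ENSMUSG00000079012, chromosome 12, 104304745 to 104360516), a serine protease inhibitor, had no read at day 0 and 256 ± 7.9 CPM at day 3, at least 4752-fold higher. Its relative Serpina3n went from 0.342 ± 0.089 to 3802 ± 116 CPM, and Serpina3f from 0.0734 ± 0.037 to 41.6 ± 3.9 CPM. Lcn2, an iron-siderophore binding protein of innate immunity, went from 0.139 ± 0.13 to 2320 ± 58 CPM. The serum amyloid gene Saa3 went from 6.66 ± 2.2 to 16400 ± 369 CPM and was the most abundant transcript of every day 3 library. Saa1 rose at least 301-fold and the B-cell chemokine Cxcl13 at least 325-fold from no read at day 0. Jaml, an adhesion molecule of leukocytes, rose 4014-fold from 1 read (counting interval 720 to 158586). The metalloreductase gene Steap4 went from 0.274 ± 0.20 to 138 ± 4.8 CPM. edgeR adjusted p-values of these genes were at most 5.11e-15.

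The genes that fell most on induction included several of myeloid cells. The fractalkine receptor gene Cx3cr1 (ENSMUSG00000052336, chromosome 9, 119730682 to 119898945) fell from 83.4 ± 4.1 to 0.0687 ± 0.12 CPM. The macrophage elastase gene Mmp12 fell from 308 ± 41 to 2.42 ± 0.54 CPM, the beta-glucan receptor gene Clec7a from 31.0 ± 4.5 to 0.965 ± 0.36 CPM, and Itgax, which encodes CD11c, from 15.0 ± 1.6 to 0.591 ± 0.37 CPM. The T-cell co-receptor gene Cd28 fell from 17.0 ± 0.61 to 0.170 ± 0.11 CPM. Ptgs2, the inducible cyclooxygenase, fell from 175 ± 12 to 5.85 ± 1.6 CPM, and Hbegf, an EGF receptor ligand, from 40.4 ± 5.5 to 2.22 ± 0.20 CPM. Sema7a (log2 fold change −4.69), Nanos1 (−4.66) and Neurl3 (−4.58) completed the 10, whose edgeR adjusted p-values were at most 7.71e-14.

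All 19 tested genes of the glucocorticoid response list rose, and all 19 when adjusted over the list alone. They included Fkbp5, a co-chaperone of the glucocorticoid receptor (8.87-fold), Tsc22d3, which encodes GILZ (11.2-fold), and the pyruvate dehydrogenase kinase gene Pdk4 (8.72-fold). The list was called by camera (adjusted p = 2.92e-12) and also with an estimated correlation (adjusted p = 0.0151). The medium held dexamethasone, a synthetic glucocorticoid. Of 24 cell-cycle genes 23 fell, and 23 when adjusted over the list alone, among them the proliferation marker Mki67 (to 0.186 times the day 0 level), Top2a (0.288) and Rrm2 (0.294), with E2f1 at −0.01. All 17 interferon response genes rose, and 17 when adjusted over the list alone, among them Irf7 (24.0-fold), Bst2 (4.74-fold) and Ifit1 (6.56-fold). Of 16 inflammation genes 11 rose and 3 fell, with the same counts when adjusted over the list alone. Beside Lcn2 and Saa3, Cxcl5 rose 40.0-fold, while Ptgs2 fell. The camera adjusted p was 2.92e-12 for the cell cycle, 4.93e-07 for the interferon response and 0.00749 for inflammation. These 3 calls were lost with an estimated correlation (adjusted p = 0.219, 0.435 and 0.235).

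Of 16 tested osteoblast differentiation genes, 8 rose and 4 fell on induction, and the same numbers when adjusted over the list alone. Ibsp, which encodes bone sialoprotein, rose 7.34-fold and Spp1, which encodes osteopontin, 2.17-fold, while Tnfrsf11b, which encodes osteoprotegerin, fell to 0.171 and Atf4 to 0.659 times the day 0 level. Alpl, the bone alkaline phosphatase, rose 1.87-fold and the osteoblast transcription factor Runx2 1.23-fold. Sp7 (0.25, adjusted p = 0.23) and Col1a1 (0.11, adjusted p = 0.14) did not pass. The list as a whole was not called (camera adjusted p = 0.437). It held 25 genes, and those not tested had few reads, at most 35 in any group (Msx2, day 0). Among them, Bglap had 3, 2 and 0 reads in the day 0, day 3 control and mutant groups, Dmp1 4, 0 and 2, and Ifitm5 8, 29 and 24. Of 19 periosteal progenitor genes, 12 rose and 5 fell, also when adjusted over the list alone. Ly6a, which encodes SCA1, rose 15.6-fold, the chemokine gene Cxcl12 7.67-fold and Pdgfra 7.86-fold, and Postn, which encodes periostin, rose 3.25-fold. This list was called (camera adjusted p = 0.0269), but not with an estimated correlation (adjusted p = 0.219). Of 33 collagen matrix genes 13 rose and 15 fell, also when adjusted over the list alone, with Dcn, which encodes decorin, at a log2 change of 3.17 and Thbs1, which encodes thrombospondin 1, down to 0.258 times the day 0 level. That list was not called (camera adjusted p = 0.973).

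Markers of other cells also moved. The macrophage genes were abundant throughout, with Lyz2 at a mean of 11525 CPM over the 9 libraries. Of 15 tested macrophage genes 10 rose and 3 fell, and the same when adjusted over the list alone. Lyz2 rose (log2 change 0.59), and Adgre1, which encodes F4/80, rose 2.76-fold. The list was not called (camera adjusted p = 0.061). Of 10 smooth muscle and pericyte genes 8 fell and 2 rose, also over the list alone, with Acta2 at 0.279 and Myl9 at 0.415 times the day 0 level (camera adjusted p = 0.0134, but adjusted p = 0.297 with an estimated correlation). Of 6 osteoclast genes 2 rose and 4 fell, also over the list alone, and the list was not called (camera adjusted p = 0.437). Over all 13013 genes, 8522 were called by edgeR, 4304 higher and 4218 lower. Of these, 1410 rose and 960 fell at least 2-fold. In 70.8% of genes the groups did not overlap, against 10% by chance. The day 0 group received no osteogenic medium, so the contrast holds time in culture as well as the medium.

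The second comparison asked what differed in mutant cells after the same induction. Genes of bone and its matrix were lower in the mutant. Of 16 osteoblast differentiation genes 12 were lower and 1 was higher (13 and 1 when adjusted over the list alone). Runx2 was at 0.587, Alpl at 0.450, Col1a1 at 0.591 and Col1a2 at 0.617 times the level of control cells at day 3, with edgeR adjusted p-values of at most 5e-08. Sp7, a transcription factor downstream of Runx2, was at 0.502 times and Ibsp at 0.648 times the control level. Smpd3 was 1.49-fold higher. Dlx5 (−0.51, adjusted p = 0.053), Pth1r (−0.09) and Enpp1 (0.13) did not pass. The list was called by camera (adjusted p = 1.25e-06) and with an estimated correlation (adjusted p = 0.0428). Of 33 collagen matrix genes 22 were lower and 2 higher (24 and 4 when adjusted over the list alone). Thbs1 was at 0.328, the tenascin gene Tnc at 0.366 and Col11a1 at 0.445 times the control level, and Dcn was 3.13-fold higher. This list was called (camera adjusted p = 7.28e-11), but not with an estimated correlation (adjusted p = 0.0812). Of 11 chondrocyte genes 6 were lower and none higher (6 and 1 when adjusted over the list alone), with Col2a1 at 0.115, Mmp13 at 0.520 and Sox6 at 0.331 times the control level. It was called with either correlation (camera adjusted p = 5.28e-05, and adjusted p = 0.0428 with the estimated one).

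In the same libraries, transcripts of the Y chromosome were lower. Ddx3y was at 0.402, Uty at 0.329, Kdm5d at 0.323 and Eif2s3y at 0.374 times the day 3 control level, with edgeR adjusted p-values of at most 3.23e-10, in all 3 mutant libraries. Kdm5d had 35.3, 37.6 and 40.4 CPM in the day 3 controls and 11.6, 11.7 and 13.2 CPM in the mutant. Of 15 macrophage genes 8 were higher and none lower (10 and 0 when adjusted over the list alone), with a median log2 change of 0.17 (camera adjusted p = 0.00445, but adjusted p = 0.158 with an estimated correlation). Lyz2 was at 0.01 (adjusted p = 0.92) and Adgre1 at 0.18, a call lost without any 1 of control day 3 replicates 1, 2 and 3 and mutant replicates 1 and 3. Of 10 smooth muscle and pericyte genes 7 were lower, also over the list alone, with Acta2 at 0.687 and Myl9 at 0.665 times the control level (camera adjusted p = 9.49e-06, adjusted p = 0.0812 with an estimated correlation). Of 7 skeletal muscle genes 4 were higher (5 over the list alone), with Acta1 1.53-fold and Mylpf 1.40-fold higher (camera adjusted p = 0.000269, adjusted p = 0.106 with an estimated correlation). Of 7 endothelial genes, all of low abundance, 2 were higher and none lower (4 and 0 when adjusted over the list alone), with a median log2 change of 1.08, the largest of the tested lists. Cdh5, which encodes VE-cadherin, was 3.35-fold higher, and Emcn 2.95-fold, a call lost without control day 3 replicate 1. The list was not called (camera adjusted p = 0.0752). These differences stand beside every list described for this contrast. The Y-linked genes part the 2 genotypes fully, so no difference in this contrast can be assigned to the loss of Plagl1 alone. In what follows, "deletion" and "after deletion" only name the contrast of mutant against control at day 3.

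The largest decreases in the mutant were in genes of several kinds. Trim66 (ENSMUSG00000031026, chromosome 7, 109048213 to 109107341), a chromatin reader, went from 4.77 ± 0.55 CPM in controls to 0.465 ± 0.060 CPM in the mutant, and Col2a1, the cartilage collagen, from 6.29 ± 0.36 to 0.716 ± 0.14 CPM. The glutathione-degrading enzyme gene Chac1 had a log2 fold change of −2.12 ± 0.17, Cdh3, which encodes P-cadherin, −1.95 ± 0.21, the receptor phosphatase gene Ptprz1 −1.90 ± 0.21 and Megf6 −1.79 ± 0.11. The mitochondrial folate enzyme gene Aldh1l2 was at −1.71 ± 0.09, the collagen gene Col8a2 at −1.64 ± 0.08 and Thbs1 at −1.61 ± 0.06, beside Kdm5d. Among the increases, the matrix protein gene Tnxb went from 4.30 ± 1.1 to 14.3 ± 1.2 CPM, and Agtr2, an angiotensin receptor on the X chromosome, from 25.1 ± 3.8 to 79.3 ± 1.7 CPM. Dcn (ENSMUSG00000019929, chromosome 10, 97315471 to 97354005) went from 203 ± 13 to 636 ± 6.6 CPM. The angiotensin-converting enzyme gene Ace was 2.69-fold, the glycine decarboxylase gene Gldc 2.87-fold, the protease gene Adamts15 2.81-fold, the vasopressin receptor gene Avpr1a 2.65-fold, the water channel gene Aqp1 2.64-fold and the adhesion gene Sdk1 2.54-fold higher. edgeR adjusted p-values of these genes were at most 7.39e-07. Stromelysin gene Mmp3 was 2.89-fold higher, with an edgeR adjusted p of 6.07e-08 that DESeq2 did not share (adjusted p = 0.190).

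Signalling genes of several pathways were lower in the mutant. The Wnt list and the BMP and TGF-beta list each mix ligands, receptors and antagonists, so their counts do not measure the activity of a pathway. Of 22 Wnt genes 9 were lower and 3 higher (10 and 3 when adjusted over the list alone), with Dkk3 at 0.505 and Wnt5a at 0.642 times control, and the Wnt antagonists Sfrp1 and Sfrp2 1.40-fold and 1.55-fold higher. Of 24 BMP and TGF-beta genes 10 were lower and 3 higher (12 and 5 when adjusted over the list alone), with Tgfb3 at 0.519, Inhba at 0.538 and Ccn2 at 0.639 times control, and the BMP antagonist gene Chrdl1 2.27-fold higher. Of 15 hedgehog and Notch genes 6 were lower and none higher (8 and 0 when adjusted over the list alone), among them Notch2 (0.838 times) and Smo (0.820 times). Of 19 imprinted network genes 6 were lower and 1 higher (7 and 1 when adjusted over the list alone), with Peg3 at 0.460, Mest at 0.432 and Grb10 at 0.705 times control. Camera adjusted p-values were 0.00947 for Wnt, 0.0153 for BMP and TGF-beta, 0.000961 for hedgehog and Notch and 0.000634 for the imprinted network. All 4 calls were lost with an estimated correlation (adjusted p = 0.0824, 0.123, 0.106 and 0.0812). For Wnt that correlation was −0.04, under the fixed 0.01, so a higher correlation between its genes does not account for the loss. In the larger KEGG pathways, tested after the data were seen, 29 Wnt genes were lower and 5 higher (camera adjusted p = 0.00598). The numbers were 23 and 5 for TGF-beta (0.0236) and 10 and 1 for hedgehog (0.0475). With an estimated correlation these calls were lost (adjusted p = 0.169, 0.176 and 0.282). The KEGG Notch pathway had 4 lower and 4 higher and was not called (0.796).

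Other lists were higher in the mutant. Their median log2 changes included 0.33 for inflammation, 0.17 for the cell cycle and 0.18 for oxidative phosphorylation. The lists just described as lower had medians of −0.28 (Wnt), −0.25 (BMP and TGF-beta), −0.26 (hedgehog and Notch) and −0.30 (imprinted network). Of 19 glucocorticoid response genes 8 were higher and 2 lower, also over the list alone, with a median log2 change of 0.15. Lcn2 was 1.57-fold and Mt1 1.48-fold higher, and Pdk4 was at 0.648 times control. Of 24 cell-cycle genes 9 were higher and none lower (10 and 0 when adjusted over the list alone), with Cdc20 1.54-fold and Cdk1 1.29-fold higher. The larger KEGG cell cycle pathway, tested after the data were seen, had 10 genes higher and 12 lower (camera adjusted p = 0.869). Of 16 inflammation genes 9 were higher and 2 lower (9 and 3 when adjusted over the list alone), with Il33 1.78-fold and Il1rn 1.40-fold higher. Of 14 oxidative phosphorylation genes 7 were higher and none lower (9 and 0 over the list alone), with log2 changes of 0.30 for Uqcrc1 and 0.26 for Cycs. Camera adjusted p-values were 0.0124, 0.000185, 0.0153 and 0.000185 in that order, and with an estimated correlation the calls were lost (adjusted p = 0.123, 0.238, 0.169 and 0.173). Of 19 periosteal progenitor genes 5 were higher and 7 lower (7 and 9 when adjusted over the list alone), with Thy1 1.70-fold, Ly6a 1.45-fold and Pi16 4.55-fold higher and Acta2 lower. That list was not called (camera adjusted p = 0.418).

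Over all 13013 genes edgeR called 2301 in the deletion contrast, 1034 higher and 1267 lower, of which 65 and 222 differed at least 2-fold. The count rose to 2948 without mutant replicate 3 and fell to 1479 without control day 3 replicate 2. The number higher fell to 543 without that library, to 666 without control day 3 replicate 3 and to 678 without mutant replicate 1. In 33.4% of genes the groups did not overlap, against 10% by chance. Mutant day 3 against control day 0, where genotype and induction differ together, gave 8894 called genes, 4382 higher and 4512 lower.

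**Figure D2:**
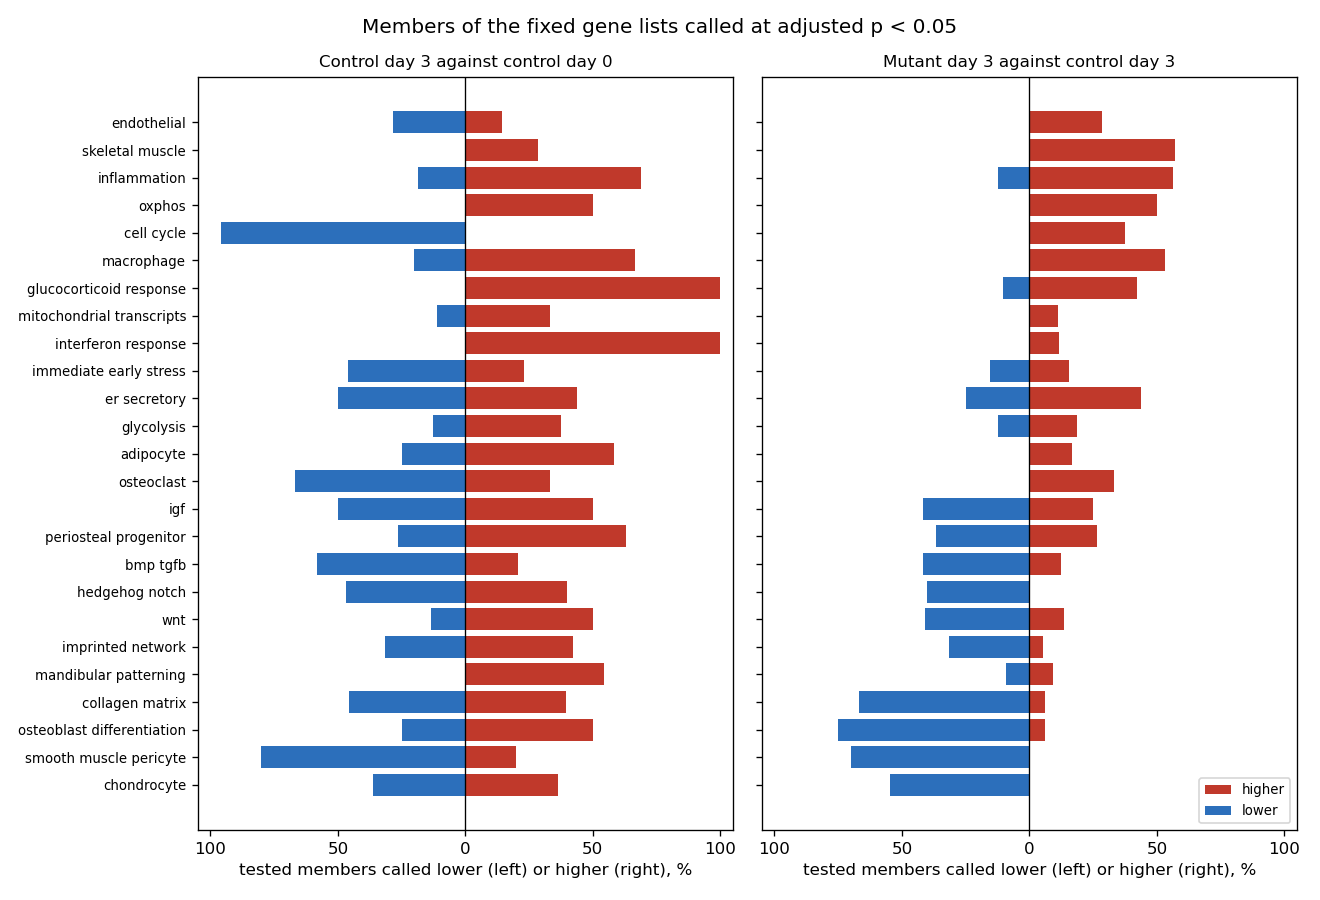
Share of the tested members of each fixed gene list (vertical axis, lists with at least 5 tested members) that edgeR called higher (red, right) or lower (blue, left), in percent, for induction in control cells (left panel) and for mutant against control at day 3 (right panel). All 19 glucocorticoid response genes rose on induction, and 12 of 16 osteoblast differentiation genes were lower in the mutant.

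The third comparison set the difference between mutant and control at day 3 beside the change on induction. No mutant library was made at day 0, so a lower or higher level in the mutant at day 3 may have been present before induction. Of the genes called in both, 640 moved in opposite directions and 1192 in the same direction. Among the opposite ones, 454 rose on induction and were lower in the mutant. Crispld2 rose from 26.8 ± 1.5 to 190 ± 6.1 CPM and stood at 89.3 ± 6.6 CPM in the mutant. Olfml3 rose 2.94-fold and was at 0.495 times control in the mutant, the gelatinase gene Mmp2 1.82-fold and 0.532 times, the osteogenic growth factor gene Clec11a 3.13-fold and 0.444 times, and the IGF-binding protein protease gene Pappa2 from 68.2 to 136 CPM and 0.465 times. Of the 8 osteoblast differentiation genes that rose on induction, 7 were lower in the mutant, namely Runx2, Alpl, Col1a2, Ibsp, Spp1, Sparc and Vdr, and of the 4 that fell 3 were lower in the mutant too. Of the collagen matrix genes 8 rose and 10 fell on induction and were lower in the mutant, and 2 rose and were higher. Among the genes that moved the same way, Dcn and Agtr2 rose on induction and were higher still in the mutant, while Thbs1, Tnc and the amino acid transporter gene Slc7a5 fell on induction and were lower still in the mutant.

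Both contrasts hold the day 3 controls, with opposite sign, so chance alone gives a negative relation. Across genes, which are not independent replicates, the log2 changes had a correlation of 0.121 and a covariance of 0.0527. Over 50 simulations of unchanged groups the means were −0.502 and −0.0121, a covariance difference of 0.0648. In those groups noise made up the whole spread, so −0.502 is not the chance value for data with many changed genes. Independent lists of these sizes would share 419 genes that rose and were lower (454 observed), 335 that fell and were higher (186), 342 that rose and were higher (654) and 411 that fell and were lower (538). In the simulations no set reached more than 1 gene, since the unchanged groups left almost no genes to call, so they give no expected overlap for these data. With 3 shared libraries the controls could not be split into sets of 2, so part of the excess of 454 over 419 may come from the shared controls. Without control day 3 replicate 2 the opposite set fell to 411 genes and the same-direction set to 774, and without control day 3 replicate 1 the correlation was 0.0733.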

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

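No gene named by the rule changed direction with its call under any alternative run for genes. No list called both in the main test and in an alternative did. The alternatives run for lists were DESeq2 size factors, the replicate block, the 2 groups alone, each library left out, an estimated correlation and fry. On induction the hedgehog and Notch list pointed down without a call in camera (adjusted p = 0.996), and fry called it up (adjusted p = 0.0452). Of 8180 values of those genes in both contrasts 7769 stayed on their side of the threshold. A log2 change of at least 1 accounts for 168 of the 334 calls lost, by its construction. DESeq2 did not call Mmp3 or Saa3 between mutant and control, at similar fold changes. The number of genes called ranged from 8217 to 8801 (induction), 2050 to 2528 (deletion) and 8588 to 9222 (mutant day 3 against control day 0) over other scalings, filters and tests, the replicate block and the 2 groups alone.

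With a log2 change of at least 1 as well, 2370 genes were called on induction (1410 higher, 960 lower), 287 after deletion (65 and 222) and 2648 between mutant day 3 and control day 0 (1408 and 1240). Leaving out each library gave 7970 to 8851 genes on induction (4026 to 4453 higher, 3934 to 4398 lower), 1479 to 2948 after deletion (543 to 1344 higher, 936 to 1604 lower) and 8378 to 8885 between mutant day 3 and control day 0. It gave 411 to 780 genes in the opposite set and 774 to 1512 in the same-direction set. The correlation ranged from 0.0733 to 0.126 and the covariance from 0.0349 to 0.0630. Fewer samples enter these fits. Some counts rose above those of the main fit, such as 2948 genes after deletion without mutant replicate 3, and the cause was not tested. Of 25 lists, 6 were called on induction and 15 after deletion. An estimated correlation left 1 and 2; fry, which asks another question, called 22 and 19. The fit to only the 2 groups compared also ended the call of the periosteal progenitor list on induction, and leaving out any library ended no list call. An alternative chosen after seeing the data, without X- and Y-linked genes, gave 2207 genes after deletion.

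The replicate numbers gave no sign of pairing. Same-numbered libraries of different groups had correlations of deviations of −0.0774 to 0.0284, against −0.105 to 0.117 for other pairs. With 3 libraries per group these values cannot exclude a pairing, by these numbers or in another order. With the replicate block 8390, 2050 and 8742 genes were called in the 3 contrasts, with 582 in the opposite set. With few changed genes planted, 22% of simulated 1.2-fold changes were recovered at this depth and with 3 libraries per group, so small effects can be missed. That share may differ where as many genes change as in these contrasts. Neither depth nor the number of libraries was varied.

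The 6 libraries of a contrast can be split in 10 ways, too few for a share under 0.05. The real split, 1 of 10, called 8522, 2301 and 8894 genes, and the highest other split 0 in each contrast. Each other split mixes the 2 groups, so a real difference raises the spread within its sides, and its values are no measure of chance. The opposite set held 640 genes, against 3 to 12 in the other splits of mutant day 3 and control day 0; in those for induction and deletion it was 0 by construction, since they called 0 genes. Of the lists, 15 were called after deletion against 8, and 6 on induction against 6, a number that 2 of the 10 splits reached.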

Other observations

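Further gene groups were measured in both contrasts. On induction 11 of 22 Wnt genes rose and 3 fell (camera adjusted p = 0.0512), while in the larger KEGG Wnt pathway 33 rose and 52 fell (0.475), and 14 of 24 BMP and TGF-beta genes fell and 5 rose (0.0512), with Ccn2 at 0.201 times the day 0 level. Of 11 mandibular patterning genes 6 rose, among them Lhx8 (2.20-fold) and Msx1 (3.42-fold), but the list was not called (0.137); after deletion Alx4 was at 0.487 times control and Lhx8 1.32-fold higher (0.148). Of 12 IGF genes 6 rose and 6 fell on induction (0.981), and after deletion 3 were higher and 5 lower (0.0752), with Igfbp2 at 0.424 and Igf1 at 0.702 times control. Of 12 adipocyte genes 7 rose and 3 fell on induction (0.288), and 2 were higher after deletion (0.325), with Fabp4 at 5.42-fold and 1.38-fold. Among 19 imprinted network genes 8 rose and 6 fell on induction (0.742), with Cdkn1c up 13.4-fold. Among 11 chondrocyte genes 4 rose and 4 fell (0.742), with Comp up 19.9-fold. Of 15 hedgehog and Notch genes 6 rose and 7 fell (0.996), with Boc up 2.91-fold and Hes1 at 0.164 times the day 0 level.

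Metabolic and stress lists were not called on induction, in that 6 of 16 glycolysis genes rose and 2 fell (0.554), 7 of 14 oxidative phosphorylation genes rose (0.366), 7 of 16 secretory genes rose and 8 fell (0.888), 3 of 9 mitochondrial transcripts rose and 1 fell (0.742), and 3 of 13 immediate early genes rose and 6 fell (0.437). After deletion the counts were 3 and 2 for glycolysis (0.325), 7 and 4 for the secretory list (0.251), 2 and 2 for immediate early genes (0.931) and 2 and 0 for the interferon response (0.0752). The mitochondrial list was called after deletion with 1 of 9 members higher (0.0234), not with an estimated correlation (adjusted p = 0.363). Osteoclast genes numbered 2 higher and 0 lower of 6 after deletion (0.798). Endothelial genes numbered 1 higher and 2 lower of 7 on induction (0.668), and 2 of 7 skeletal muscle genes rose on induction (0.600). Of the Hox, epithelial and Schwann cell lists 2, 2 and 4 genes were tested, of which 1, 2 and 3 changed on induction and 0, 1 and 0 after deletion; 0 erythroid genes were tested. Adjusted over the list alone, the counts of higher and lower genes in these 2 paragraphs were the same, except on induction for BMP and TGF-beta (6 and 14), hedgehog and Notch (7 and 7) and endothelium (1 and 1). After deletion they were 4 and 7 for IGF, 1 and 0 for the interferon response, 4 and 2 for glycolysis, 1 and 2 for mandibular patterning, 3 and 2 for immediate early genes, 2 and 0 for mitochondrial transcripts and 0 and 1 for Schwann cells. In KEGG pathways of the deposited annotation, tested after the data were seen, 51 of 312 were called on induction and 59 after deletion, and 0 in either with an estimated correlation. Nucleocytoplasmic transport had 81 genes lower and 3 higher on induction, and ECM-receptor interaction 32 lower and 4 higher after deletion. KEGG oxidative phosphorylation had 72 genes higher and 8 lower on induction (0.000965, but adjusted p = 0.596 with an estimated correlation) and 29 higher and 0 lower after deletion (1.12e-07, but adjusted p = 0.427).

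All tests below were chosen after the result was seen. For the lower osteoblast and collagen genes in the mutant, a smaller share of mesenchymal cells would lower all mesenchymal markers alike. The 12 pan-mesenchymal genes outside those lists had a median log2 change of −0.17 (quartiles −0.34 to −0.10, 6 lower and 0 higher), against −0.40 for all 47 tested genes of the 2 lists, a gap within their spread, so it may account for a part or more and stays open. A weaker response to dexamethasone would lower the glucocorticoid list, whose median was 0.15. Sex make-up cannot be told apart from genotype, since the median of the Y-linked genes was −1.51 and no genotype holds libraries of both kinds. The deletion of Plagl1, which the design names, stays open with both. Only the mutant genotype carries CTSK-iCre, so the presence of Cre cannot be told apart from the deletion either.

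Lower Y-linked transcripts in all 3 mutant libraries may come from a smaller share of male cells. The 4 X-linked homologs Kdm5c, Kdm6a, Ddx3x and Eif2s3x, which escape inactivation in mice in whole or in part, had a median log2 change of 0.21, at percentile 99.3 of 10000 random sets of matched expression. Kdm5c (0.23, edgeR adjusted p = 0.00569) was called, and Ddx3x was at 0.01. Loss or silencing of the Y chromosome in male cells stays open, since the homologs might rise to compensate for it. Xist was not analysed here.

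Macrophage genes changed on induction. A change in the share of macrophages alone would move them alike, but 3 called members, Csf1r, Mrc1 and Ptprc, fell while 10 rose, so it may be a part of the pattern, not the whole. A change of expression within macrophages stays open, as the medium holds dexamethasone, and was not tested.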
